A study of Arabidopsis thaliana with 24 samples.

How the data were processed

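RNA was measured by sequencing in leaves of 2 Arabidopsis thaliana ecotypes, Castelnuovo-12 from Italy (IT) and Rodasen-47 from Sweden (SW). Plants of each were grown in 4 regimes that cross light with temperature. Low light was 100 µmol photons per square metre and second and high light 1000. In warm regimes leaf temperature was 25 °C in the light and 20 °C in the dark, in the cool low-light regime 16 °C and 12.5 °C, and in the cool high-light regime 14 °C and 12.5 °C. The regimes are abbreviated LLW, LLC, HLW and HLC (low or high light, warm or cool). The photoperiod was 9 h, and 2 discs of 0.73 square cm from the youngest fully developed leaf were frozen at the end of the 15 h night, per the labels. Ribosomal RNA was depleted and TruSeq libraries were made, per the labels' protocols. There were 3 biological replicates in each of the 8 groups, 24 libraries in all; the labels do not say whether replicates were separate plants or separate growth runs, so p-values measure the spread between these samples.

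The deposited table holds counts per gene for 33610 gene identifiers and 1 column per library, and the authors pooled no replicates in it. The values are whole numbers whose totals differ between libraries. The lowest value in the table is 1 and no cell holds 0, so an offset was added or 0 was replaced by 1; which of these was done is not given in the sources used here. HISAT, StringTie and DESeq2 and the build TAIR10 are named per the submitters' processing notes; their versions, roles and options, and whether counting used strand, are not given in the sources used here. Both ecotypes were counted on 1 reference, so a transcript that differs in sequence from it can be counted less. Near-identical genes, among them the LHCB1 and RBCS copies, CBF1 to CBF3, COR15A and COR15B, and the resistance gene cluster with RPP4, RPP5 and SNC1, can share or exchange reads, and their values are uncertain in that respect.

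Gene symbols came from the NCBI gene table of the assembly TAIR10.1, matched by locus identifier; 28932 identifiers matched and 4678 did not. Because this is not the build named by the authors, no coordinates were taken from it. Library codes in the labels fall into a series with letters, which holds all LLW and HLC libraries, and a series with numbers, which holds all LLC and HLW libraries. A difference between the series cannot be told apart from the interaction of light with temperature, and every step of only light or only temperature sets one series against the other. The mean effects of light and of temperature and the ecotype differences are balanced over the series.

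The counts as deposited were tested with edgeR's quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) on 8 groups and all 24 libraries, which share one estimate of the spread, with TMM normalization. The filter filterByExpr (minimum count 10, minimum total 15) kept 17709 genes. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05. Fold changes are log2 values with standard errors (SE). Levels are counts-per-million (CPM), given as mean ± SD of 3 libraries. A gene at the lowest value in every library of a group gave a fold only as a bound, computed against 3 counts per library, and none where such groups are averaged with others. Floors cover counting error only, while SEs and SDs hold the spread between libraries.

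The comparisons, their tests, the rule for the named genes, the gene lists and most of the alternatives were fixed before the data were examined. Departures from this are given below. For HLC against LLW, light, temperature and SW against IT, the named genes were the 6 risen and 6 fallen genes of largest change with an adjusted p below 0.05, a mean log2 CPM of at least 3, a symbol, and the same direction in every stratum. For SW against IT the 3 highest genes in each direction with a mean CPM below 0.1 under the other label were added. Up to 4 members of each list with the smallest adjusted p, and CBF1, CBF2, CBF3, PSBS and FLC, were named in each comparison. For HLC against LLW, the genes of largest change were ranked on the mean of both labels, a contrast added after the data were seen. List members there had to change in the same direction in both labels, where any did. They were ranked by the larger of the adjusted p in IT and in SW. The fixed rule stated neither this condition nor this ranking, and the list genes named there favour agreement between labels. For the differences between ecotypes and for light by temperature, the 5 genes of smallest adjusted p in each direction were taken. The report prints part of these.

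There were 22 lists with 374 memberships: cold-regulated genes, the flavonoid pathway, light-harvesting antenna, nuclear photosystem subunits, the Calvin-Benson cycle, photoprotection, starch, sucrose and sugar export, dark- and starvation-induced genes, the clock, salicylic acid defence, jasmonate, glucosinolates, heat shock, flowering time, ribosome biogenesis, shade, senescence, and markers of epidermis, guard cells, phloem and xylem. Each was counted with p adjusted over all genes and with p adjusted over the list alone, and tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation; fry was run as a self-contained test.

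After the data were seen, contrasts were added that average both ecotype labels, that exchange the LLW reference groups, that use the groups of one label only, and that set IT_HLW against SW_LLC and, for the cold list, SW_HLW against IT_LLC. All were added because the data and the ecotype labels did not match. A transcript was called on in a group when every library had at least 20 counts and off when every library had at most 2. Also after the data were seen, transcripts were chosen without the libraries they were then looked up in. IT_HLC replicate 3, and each SW_HLC library for comparison, was then placed between the HLC groups. This used genes with at least 5 CPM in one group and at least 4-fold more than in the other. List tests were planned for HLC against LLW in IT and in SW, light, temperature and SW against IT. Those on other comparisons, among them the single-factor steps and SW against IT in each regime, were outside that plan. After the data were seen, camera was also added for the differences between ecotypes and without IT_HLC replicate 2 or 3. The alternatives were DESeq2, RLE size factors, no filter on low counts, removal of 283 organelle and ribosomal RNA genes, a fold threshold, a replicate block, fits to 6 libraries, models with the library series, and leaving out each library. Added after the data were seen were 1 subtracted from every value and values of 1 set to 0.

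The procedure was tested on simulated counts for 17709 genes, drawn from the real means and library sizes with 200 genes changed. For HLC against LLW in IT it called 9% of genes changed 1.5-fold, 35.8% of those changed 2-fold and 83.3% of those changed 4-fold. For the light effect the shares were 59.7%, 82.1% and 100%, and for SW against IT 64.2%, 88.1% and 95.5%. No changed gene was called in the wrong direction, and 2 unchanged genes were called in the first comparison and 7 in each of the others. In the simulated light effect, camera called the raised list at an adjusted p of 3.96e-110 and 0 of 20 unchanged lists. Genes were drawn independently, so this does not test camera where genes are correlated. The search for on and off transcripts recovered 20 of 20, but these were set to the lowest value in well-expressed genes, which made recovery near certain. With only 200 of 17709 genes changed, far fewer than the real data call, the shares above need not carry over. No pair of replicates agreed within sampling noise: the chi-square per degree of freedom was 9.2 to 374.8. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.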

Results

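Leaf transcript levels were measured in 24 libraries from the Arabidopsis thaliana ecotypes Castelnuovo-12 (IT) and Rodasen-47 (SW), grown in low or high light and warm or cool air. Each of the 8 groups held 3 libraries. Total counts ran from 10967425 in IT_HLW replicate 1 to 17467653 in SW_LLC replicate 2. Plastid transcripts took 54.84% to 67.99% of each library. The median biological coefficient of variation per gene was 0.165.

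The ecotype labels did not separate the libraries. The first component of the 2000 most variable genes held 35.7% of the variance and ran from 25.5 to 73.3 in the libraries labelled IT_LLC, IT_HLC, SW_LLW and SW_LLC, and from -62.5 to -22.5 in those labelled IT_LLW, IT_HLW, SW_HLW and SW_HLC. The second component held 26.2% and ran from 39.7 to 77.1 in the 6 HLC libraries, with no other library above -2.4. The third component held 11.4% and reached 26.9 to 62.1 in the 3 SW_LLC libraries.

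**Figure D1:**
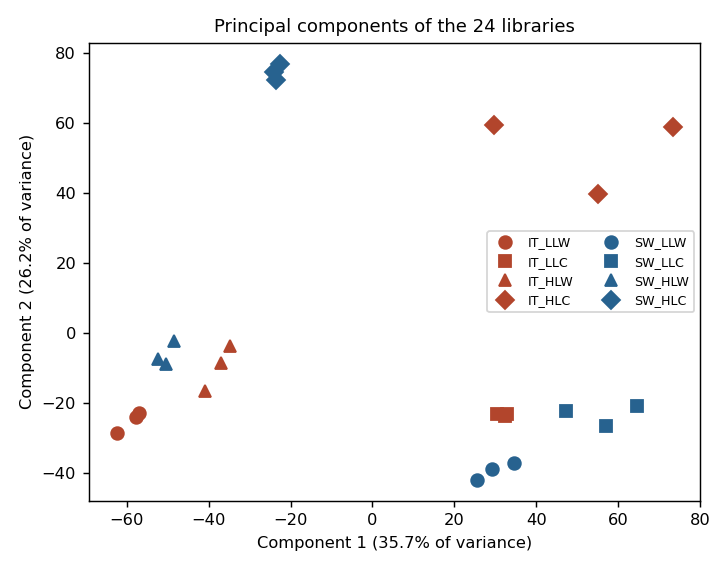
Scores of the 24 libraries on components 1 (35.7% of variance) and 2 (26.2%), without units; color gives the ecotype label, red IT and blue SW, and shape the regime. The 12 libraries with positive component 1 scores include both labels, and the 6 HLC libraries lie above the others on component 2.

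Transcripts that were present in some groups and absent from others fell into the same division. No transcript was on in all groups of one ecotype label and off in all groups of the other. With IT_HLC replicate 3 set aside, 52 transcripts were on or off in every group. A first set of 28 was on in IT_LLC, IT_HLC, SW_LLW and SW_LLC and off elsewhere, and a second set of 17 was on in the other 4 groups. The first set held QQS, an orphan gene tied to starch content, and ADR1-L3, a relative of helper immune receptors. The second held the immune receptor genes CSA1 and DAR4, and THI2.2, which encodes a thionin. These members were chosen after their values were seen. With all 24 libraries the search found 30 transcripts, of which 25 followed this division.

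**Figure D2:**
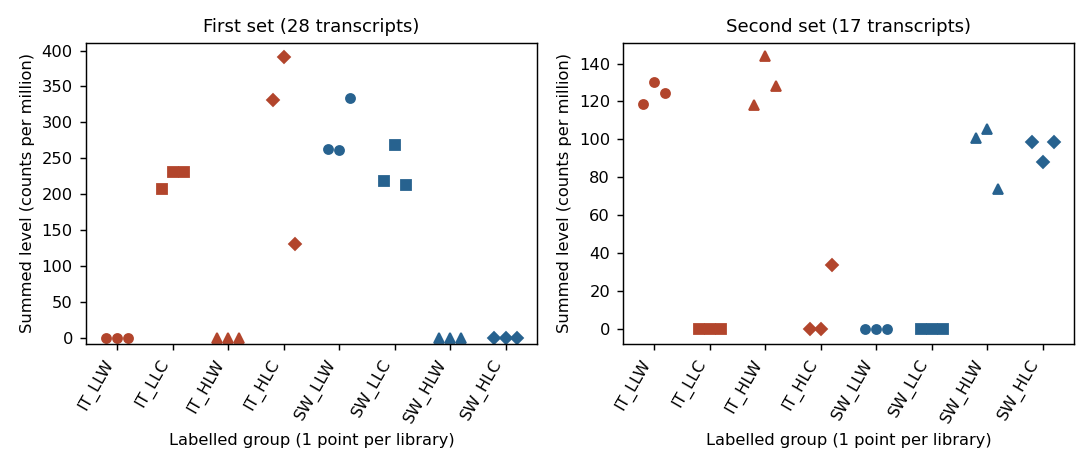
Summed level in CPM (counts-per-million) of the 28 transcripts of the first set (left) and the 17 of the second (right), 1 point per library, red IT and blue SW. IT_HLC replicate 3 holds both, at 131.4 and 33.8 CPM.

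The library labelled IT_HLC replicate 3 carried both sets. Its first-set transcripts stood at a median of 48.4% and its second-set transcripts at a median of 31% of the level in the libraries that carry each set. The other IT_HLC libraries had first-set sums of 331.5 and 391.3 CPM. After the data were seen, 35 transcripts were chosen without the SW_LLW and IT_HLC libraries. They were on in IT_LLW, IT_HLW, SW_HLW and SW_HLC and off in IT_LLC and SW_LLC. The 17 of the second set, already chosen as off in SW_LLW and the other IT_HLC libraries, are among them. The summed level of all 35 in IT_HLC replicate 3 was 32.7% of that in the groups chosen as on, with 35 above 2 counts. It was 1.28% in IT_HLC replicate 1, with 13 above 2 counts, and 0.195% to 0.449% in IT_HLC replicate 2 and the SW_LLW libraries. Nuclear ribosomal RNA took 7.87% of IT_HLC replicate 3, the highest share of any library. Because of this division, groups below are named by their labels, and every ecotype direction is that of the labels.

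The extreme regimes, HLC against LLW, were compared within each label and as the mean over both labels. Within each label they carried different transcript sets, so regime and set coincide there. The mean, added after the data were seen, sets equal numbers of first-set and second-set groups on each side. Among the named genes that rose were cold-regulated ones. COR15A (AT2G42540), which encodes a membrane-protecting chloroplast protein, rose by 7.30 ± 0.41 on the log2 scale (SE; adjusted p = 3.53e-11), from 2.06 ± 0.474 to 364 ± 63.3 CPM in IT and from 1.76 ± 0.321 to 250 ± 119 CPM in SW (SD, n = 3). RD29A (AT5G52310), a cold and dehydration marker, rose by 7.52 ± 0.45 (adjusted p = 7.99e-11). DELTA-TIP (AT3G16240), a vacuolar water channel, fell by 6.63 ± 0.39 (adjusted p = 6.87e-11). Also lower were EXO (AT4G08950) at -5.74, FLA9 (AT1G03870) at -4.64 and TCH4 (AT5G57560), a xyloglucan-modifying enzyme, at -4.45.

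Of 17709 genes tested, 9678 changed in IT (5066 higher, 4612 lower) and 8912 in SW (4388 higher, 4524 lower); 9881 changed in the mean (5041 higher, 4840 lower). Other genes named in the mean were COR15B (AT2G42530), at 6.38 ± 0.31, PR1 (AT2G14610), the salicylic acid marker, at 5.92 ± 0.72, GRP7 (AT2G21660), an RNA-binding protein, at 5.71 ± 0.44, and LURP1 (AT2G14560), a defence gene, at 5.07 ± 0.62. KCS12 (AT2G28630), a fatty acid elongase, fell by 6.08 ± 0.33 and GASA6 (AT1G74670), a gibberellin-regulated gene, fell by 5.66. COR15A and COR15B can share reads. The mean plastid share was also lower in HLC, 57.74% ± 2.09 in IT and 57.43% ± 2.41 in SW against 62.66% ± 0.47 and 59.23% ± 2.9 in LLW (SD, n = 3). In SW the libraries of the regimes overlapped, and these shares were not tested.

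Of 29 cold-regulated genes tested, 25 rose and 2 fell in the mean, and adjusted over the list alone 26 rose and 2 fell; the list stood above the other genes (camera adjusted p = 2.75e-11, and adjusted p = 0.0116 with an estimated correlation). COR28 was at least 56.9-fold higher in IT and 48.3-fold higher in SW. The cold transcription factor CBF3 rose by 5.30 ± 0.42 and CBF2 by 4.21 ± 0.28, and CBF1 was at least 9.59-fold higher in IT and 2.99-fold higher in SW; their sequences are alike and their values uncertain. Of 17 starch genes 16 rose, also adjusted over the list alone, and none fell (camera adjusted p = 6.45e-08, and adjusted p = 0.033 with an estimated correlation). ISA3 (AT4G09020), a debranching enzyme, rose by 4.79 ± 0.20 (adjusted p = 6.63e-13), the branching enzyme SBE2.1 by 3.95 and the glucan phosphatase SEX4 by 3.22.

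All 7 shade and thermomorphogenesis genes fell, also adjusted over the list alone, with ATHB2 at -2.82; HFR1 fell to the table's lowest value in both labels, at least 48.1-fold in IT, and IAA29 was at least 31.6-fold lower in SW (camera adjusted p = 0.000551, but adjusted p = 0.0851 with an estimated correlation). Of 11 jasmonate genes 8 rose, also adjusted over the list alone, with the synthesis genes AOC2 at 3.59 and LOX2 at 2.90 and the defensin PDF1.2A at 6.43 (camera adjusted p = 0.00671; adjusted p = 0.559 with an estimated correlation). Of 21 antenna genes 13 fell and 2 rose, 3 adjusted over the list alone; LHCB1.2 stood at -1.11 and LHCA3 at -1.14, while LHCB4.3 rose by 3.39 ± 0.29 (camera adjusted p = 0.0294; adjusted p = 0.686 with an estimated correlation). Of 29 photosystem subunits 14 fell and 1 rose, also adjusted over the list alone, with PETE1, plastocyanin, at -1.32 (camera adjusted p = 0.0166; adjusted p = 0.696 with an estimated correlation). Phloem markers fell for 8 of 10 and xylem markers for 5 of 5, also adjusted over the list alone, with the sieve-element gene SEOR1 at -2.60 and the xylem protease XCP2 at -2.94. By camera these had adjusted p = 0.0166 and 0.0355, and adjusted p = 0.559 for both with an estimated correlation.

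**Figure D3:**
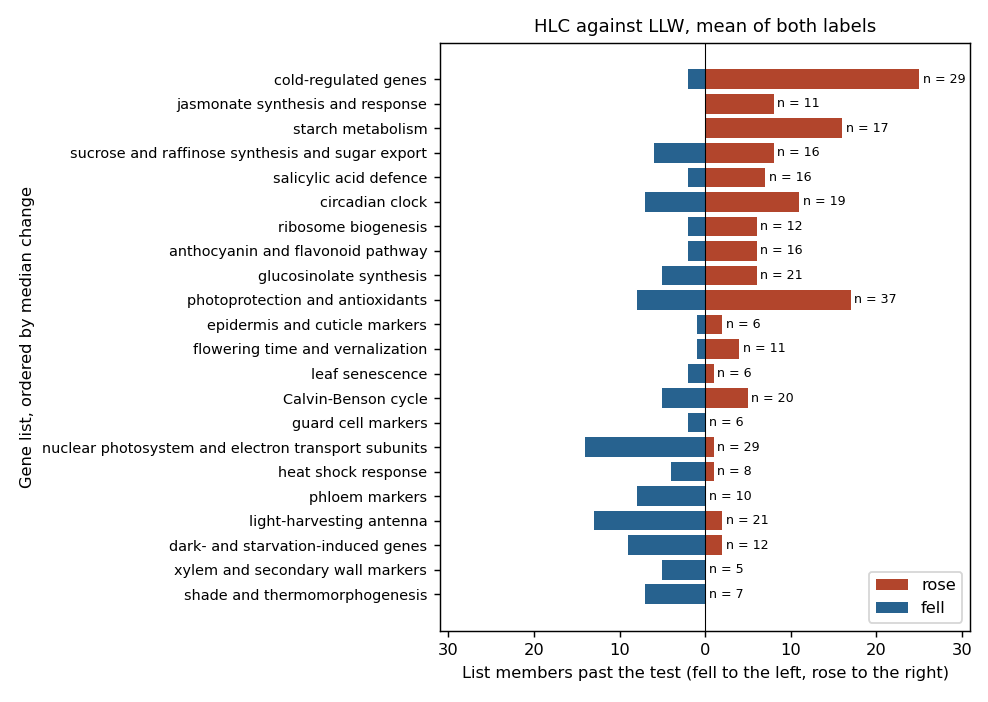
Members of each of the 22 lists that rose (red, right) or fell (blue, left) in HLC against LLW as the mean of both labels; n is the number tested. Of 29 cold-regulated genes 25 rose, and 7 of 7 shade genes fell.

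The clock gene TOC1 (AT5G61380) rose by 4.78 ± 0.17 (adjusted p = 2.2e-13) and FKF1 by 6.76 ± 0.28, among 11 clock genes that rose and 7 that fell of 19. The early light-induced proteins ELIP1 and ELIP2 rose by 8.13 and 7.33, and the lipocalin LCNP by 3.38, among 37 photoprotection genes of which 17 rose and 8 fell. ASN1, asparagine synthetase, fell by 5.06 among 12 dark-induced genes, of which 9 fell and 2 rose. The sugar genes SUS1 and SPS4F rose by 4.28 and 3.06, with 8 rising and 6 falling of 16. Adjusted over the list alone, 12 clock, 18 photoprotection and 3 dark-induced genes rose; camera gave adjusted p = 0.0833, 0.0624, 0.0624 and 0.0833 for these 4 lists. The remaining lists were not called either. Salicylic acid genes rose for 7 and fell for 2 of 16, flavonoid genes 6 and 2 of 16, Calvin-Benson genes 5 and 5 of 20 and glucosinolate genes 6 and 5 of 21. Flowering genes rose for 4 and fell for 1 of 11, ribosome biogenesis genes 6 and 2 of 12 and epidermis markers 2 and 1 of 6. Heat shock genes rose for 1 and fell for 4 of 8, senescence genes 1 and 2 of 6 and guard cell markers 0 and 2 of 6. Adjusted over the list alone, 7 ribosome biogenesis genes rose and the other counts did not move. The Calvin-Benson list had a median of -0.04 with a test in the upward direction, and the senescence list a median of 0.02 with a mean of -0.35 and a test in the downward direction.

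**Figure D4:**
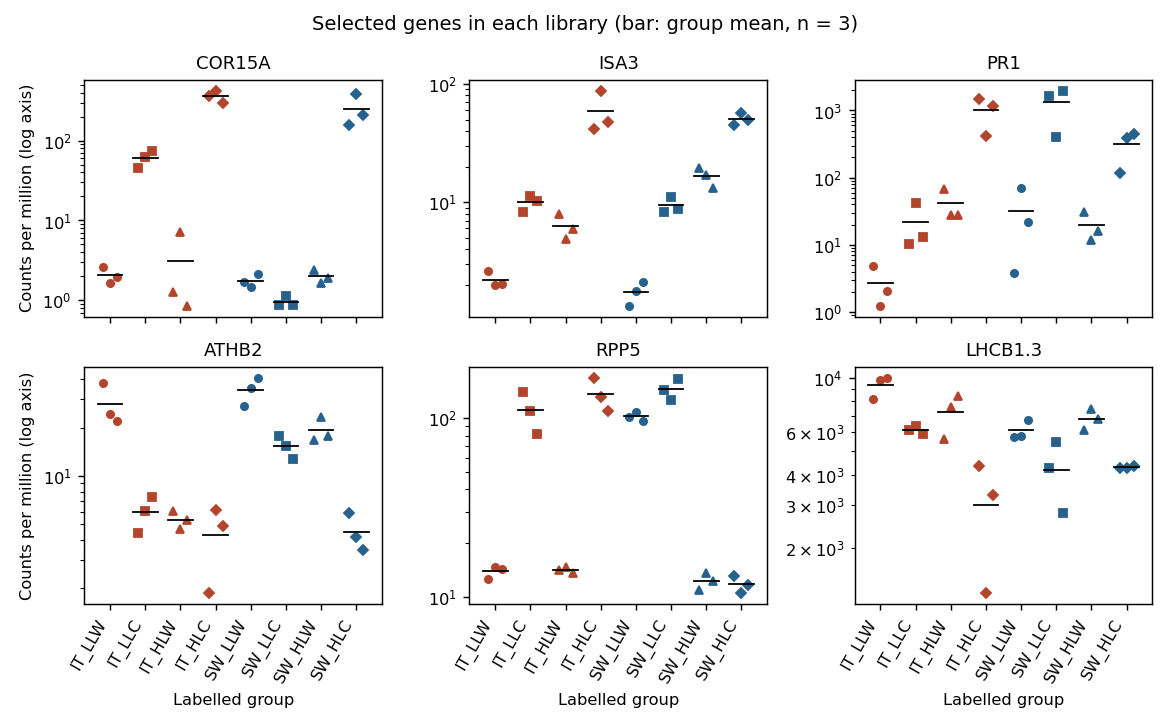
Level of COR15A, ISA3, PR1, ATHB2, RPP5 and LHCB1.3 in every library, in CPM on log axes; points are libraries, bars group means (n = 3), red IT and blue SW. RPP5 is at 103 CPM in SW_LLW and 13.9 CPM in IT_LLW, and at 11.8 CPM in SW_HLC and 136 CPM in IT_HLC.

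The lists were also counted within each label. In IT, 17 of 21 antenna genes fell and 1 rose, and 22 of 29 photosystem subunits fell (camera adjusted p = 3.55e-05 and 1.07e-06; adjusted p = 0.544 for both with an estimated correlation). IT_HLC replicate 2 had the largest residual SD of the libraries, 0.479, and an LHCB1.3 level of 1310 CPM against 4370 and 3320 CPM in the others of its group; without it the antenna counts stayed the same, and 22 photosystem subunits fell and 1 rose. In SW, 3 antenna genes and 4 photosystem subunits rose, 3 each adjusted over the list alone, and none fell. Phloem markers fell for 9 of 10 in IT, and in SW 3 rose and 1 fell. Salicylic acid genes rose for 8 of 16 in IT (camera adjusted p = 0.0295, adjusted p = 0.662 with an estimated correlation, and adjusted p = 0.085 without IT_HLC replicate 3). In SW, 10 of 16 sugar genes rose (camera adjusted p = 0.000961; adjusted p = 0.0608 with an estimated correlation). Tested on the difference between labels, which was added after the data were seen, antenna, photosystem and phloem lists had camera adjusted p = 3.5e-06, 1.72e-08 and 6.29e-05, and adjusted p = 0.521 for all with an estimated correlation. Salicylic acid and sugar lists were not called there (camera adjusted p = 0.105 and 0.0621). Both the comparisons within a label and the difference between labels coincide here with the transcript sets.

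The difference between the labels in HLC against LLW sets IT_LLW and SW_HLC, with the second transcript set, against IT_HLC and SW_LLW, with the first. It therefore coincides with the sets and cannot be told apart from them. It was past the test for 6566 genes, 3311 higher in SW and 3255 lower. The resistance gene RPP5 (AT4G16950) had the smallest adjusted p among those lower, -6.41 ± 0.27 (adjusted p = 2.2e-13), at 3.29 in IT and -3.12 in SW. RPP5 went with the transcript sets, at 81.9 to 168 CPM in libraries of first-set groups and 10.5 to 14.7 CPM in the others. Its neighbours RPP4 (AT4G16860) and SNC1 (AT4G16890) differed by -3.72 ± 0.23 and -3.91 ± 0.24; the 3 genes are near copies and their values are uncertain. WRR4 (AT1G56510), a white rust resistance gene, went the other way at 6.93 ± 0.56, and P5CR, a proline synthesis enzyme, at 2.73 ± 0.18. Across 17709 genes, which are not independent replicates, the change in IT and the change in SW had r = 0.20 (Spearman 0.28). With the LLW groups exchanged, IT_HLC against SW_LLW and SW_HLC against IT_LLW had r = 0.75 (Spearman 0.72); this exchange was chosen after the data were seen.

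The light comparison averaged over temperatures and labels. CYP72A11 (AT3G14650), a cytochrome P450, rose by 3.08 ± 0.20 (adjusted p = 1.04e-09), COR15A by 2.85 ± 0.26, CORI3 (AT4G23600), a cystine lyase, by 2.84 ± 0.31, and SOC1 (AT2G45660), a promoter of flowering, by 2.60 ± 0.22. DELTA-TIP fell by 3.06 ± 0.24, the ethylene response factor EBP (AT3G16770) changed by -2.86 ± 0.20, PKS4 (AT5G04190), a phytochrome signalling gene, by -2.38, and SKU5 (AT4G12420), a cell wall gene, by -1.93. The flowering repressor FLC (AT5G10140) fell by 1.70 ± 0.30 (adjusted p = 0.000136). In all, 8556 genes changed, 4003 higher and 4553 lower in high light. With the library series fitted apart, the letters give HLC against LLW and the numbers HLW against LLC. Light and temperature change together in each. In the numbers both HLW groups carried the second transcript set and both LLC groups the first, so that fit also coincides with the sets. A gene was counted for light when it passed in both series with the same sign, and 1230 did. Of the 4 low-light groups 3 carried the first transcript set, and of the 4 high-light groups 1 did, so the light mean is not balanced over the sets. CYP72A11 went with the sets: it was at 1.98, 2.75 and 1.5 CPM in IT_LLC, SW_LLW and SW_LLC. It was at 14.5 ± 12.3 CPM in IT_HLC (SD, n = 3). The second-set groups had 33.9 CPM in IT_LLW, 36.7 in IT_HLW, 47.2 in SW_HLW and 58 in SW_HLC.

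Of 29 cold-regulated genes 22 rose and 2 fell with light (camera adjusted p = 2.17e-08), and of 17 starch genes 15 rose (camera adjusted p = 1.12e-08), 16 adjusted over the list alone. Both had adjusted p = 0.0295 with an estimated correlation; without IT_HLC replicate 3 these were adjusted p = 0.0836 and 0.0601. In warm air alone, from LLW to HLW, 6 of the cold-regulated genes rose and 3 fell in IT, and 6 rose and 2 fell in SW (camera adjusted p = 0.352 and 0.502). In cool air, lit leaves were at 14 °C in high light and 16 °C in low light, so light and leaf temperature differ together there. ISA3 rose by 2.43 ± 0.13 and PHS2, a glucan phosphorylase, by 1.92. Shade genes fell for 6 of 7, 7 adjusted over the list alone, and ribosome biogenesis genes fell for 8 of 12, with FIB1, fibrillarin, at -0.81. Sugar genes rose for 8 and fell for 1, epidermis markers rose for 5 of 6 with the wax gene CER1 at 3.21 ± 0.38, and jasmonate genes rose for 5 with AOS at 1.37. Camera gave adjusted p = 0.00422 for shade and for sugar, 0.00366 for epidermis, 0.0178 for jasmonate and 0.0214 for ribosome biogenesis. These were adjusted p = 0.164, 0.105, 0.266, 0.628 and 0.628 with an estimated correlation. Photoprotection genes rose for 17 and fell for 5, 6 adjusted over the list alone, clock genes 12 and 7 and glucosinolate genes 10 and 3, 4 adjusted over the list alone (camera adjusted p = 0.031, 0.031 and 0.0389). These were adjusted p = 0.628, 0.628 and 0.782 with an estimated correlation.

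Light was also compared within each label. In IT, where both light levels hold 1 group of each transcript set, 11 of 16 salicylic acid genes rose and 1 fell, and in SW, where light and transcript set coincide, 14 fell, 15 adjusted over the list alone. The camera test gave adjusted p = 4.87e-05 and 0.000752, and adjusted p = 0.48 and 0.393 with an estimated correlation. Photosystem subunits fell for 14 of 29 in IT, 15 adjusted over the list alone, and rose for 14 in SW (camera adjusted p = 2.45e-05 and 0.00077; adjusted p = 0.574 and 0.514 with an estimated correlation). For the difference between labels, these lists had camera adjusted p = 3.72e-08 and 3.32e-08, and adjusted p = 0.339 and 0.365 with an estimated correlation. Light changed 6002 genes in IT and 8995 in SW. The difference between the labels was past the test for 6719 genes (3137 higher in SW, 3582 lower), with the smallest adjusted p in each direction for RPP5 at -3.50 and P5CR at 1.38.

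The comparison of cool with warm air averaged over light and labels. PR1 rose by 4.25 ± 0.47 (adjusted p = 4.72e-07), LURP1 by 3.83 ± 0.41, COR15B by 3.57 ± 0.20, GRP7 by 3.31 ± 0.28, the thaumatin-like PR5 (AT1G75040) by 2.98 ± 0.33 and the lipase PLA2A (AT2G26560) by 2.82 ± 0.21. DELTA-TIP fell by 3.57 ± 0.24 (adjusted p = 7.22e-10), the plasma membrane water channel PIP1C (AT1G01620) changed by -2.70 ± 0.21, FLA9 by -2.56 and the cell wall gene DGR2 (AT5G25460) by -2.48. In all, 9992 genes changed, 5375 higher and 4617 lower in cool air. With the library series fitted apart, 2300 genes passed in both with opposite signs, the rule used there for temperature. The first transcript set was carried by 3 of the 4 cool groups and 1 of the 4 warm groups. PR1 stood at 1340 ± 828 CPM in SW_LLC and 1020 ± 540 CPM in IT_HLC, against 22 ± 17.8 CPM in IT_LLC and 318 ± 177 CPM in SW_HLC (SD, n = 3).

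Of 29 cold-regulated genes 23 rose with cool air and none fell (camera adjusted p = 2.22e-09; adjusted p = 0.0326 with an estimated correlation, and 0.124 without IT_HLC replicate 3). Salicylic acid genes rose for 12 of 16, with WRKY54 at 2.41 and PR2, a glucanase, at 2.76, and ribosome biogenesis genes rose for 10 of 12, with the nucleolar gene NOP56 at 1.13; camera gave adjusted p = 0.00161 for both, and adjusted p = 0.516 and 0.431 with an estimated correlation. Starch genes rose for 13 and fell for 1 (camera adjusted p = 0.000241; adjusted p = 0.147 with an estimated correlation). Antenna genes fell for 15 and rose for 1, with LHCB3 at -1.23, and photosystem subunits fell for 21 and rose for 1, 22 falling adjusted over the list alone. Camera gave adjusted p = 0.00161 and 0.00045, and adjusted p = 0.579 for both with an estimated correlation. Shade genes fell for 6 of 7, phloem markers for 9 of 10 with the sugar exporter SWEET11 at -1.16, and xylem markers for 5 of 5 with the cellulose synthase CESA7 at -1.32. Tested with camera, these lists had adjusted p = 0.000886, 0.00161 and 0.0111, and adjusted p = 0.147, 0.292 and 0.431 with an estimated correlation. Dark-induced genes fell for 8 and rose for 2, jasmonate genes rose for 5, and glucosinolate genes fell for 6 and rose for 1 (camera adjusted p = 0.0212, 0.0472 and 0.0475). These were adjusted p = 0.487, 0.579 and 0.602 with an estimated correlation, and the glucosinolate call had adjusted p = 0.0642 without IT_HLC replicate 3.

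Within the labels, cold-regulated genes rose for 21 of 29 in IT, 22 adjusted over the list alone, and for 20 in SW, 21 adjusted over the list alone, where 1 fell (camera adjusted p = 6.29e-10 and 3.31e-06; adjusted p = 0.219 and 0.288 with an estimated correlation). Salicylic acid genes rose for 15 of 16 in SW (camera adjusted p = 8.8e-07; adjusted p = 0.288 with an estimated correlation). Cool air changed 8696 genes in IT, where temperature and transcript set coincide, and 7113 in SW, where they are balanced. The difference between labels was past the test for 4440 genes (2422 higher in SW, 2018 lower), with NPR3, a salicylic acid receptor, at 3.15 ± 0.29 and the cold gene KIN2 at -3.73 ± 0.34. KIN2 stood at 187 ± 18.5 CPM in IT_LLC and 9.14 ± 4.59 CPM in SW_LLC (SD, n = 3).

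The test of light by temperature asked where both factors together departed from the sum of each, and 6542 genes passed it (3371 higher, 3171 lower). The ethylene signalling genes EBF1 and ERS1 had interactions of 2.40 ± 0.14 and 2.14, the zinc finger gene GATA4 of 3.44 and the acid phosphatase PAP12 of 3.84. KCS12 had an interaction of -5.66 and the clock gene PRR7 of -2.06. This interaction coincides with the library series and cannot be told apart from a difference between the series.

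The single-factor steps all set one library series against the other. From LLW to LLC, 16 of 29 cold-regulated genes rose and 1 fell in IT, 17 rising adjusted over the list alone (camera adjusted p = 0.00071; adjusted p = 0.671 with an estimated correlation), while COR15A went from 2.06 ± 0.474 to 61.1 ± 14.6 CPM (SD, n = 3). In SW the same step raised 16 of 16 salicylic acid genes and lowered 17 of 21 glucosinolate genes (camera adjusted p = 2.33e-09 and 5.38e-07; adjusted p = 0.568 and 0.726 with an estimated correlation), with COR15A at 0.95 ± 0.144 CPM in SW_LLC. From LLW to HLW, salicylic acid genes rose for 9 in IT (camera adjusted p = 2.35e-05; adjusted p = 0.857 with an estimated correlation), and in SW ribosome biogenesis genes fell for 11 of 12 and rose for 1 (camera adjusted p = 4.6e-05; adjusted p = 0.348 with an estimated correlation). These steps changed 7146, 7117, 3893 and 7574 genes. From LLC to HLC, cold-regulated genes rose for 22 in IT, and in SW 20 rose and 2 fell while 15 of 16 salicylic acid genes fell (7107 and 9290 genes in all). Adjusted over the list alone, 3 cold-regulated genes fell and 1 salicylic acid gene rose in SW. From HLW to HLC, 23 cold-regulated genes rose in IT, and in SW 22 rose and 3 fell (7940 and 7203 genes); adjusted over the list alone 24 rose in each. Camera gave adjusted p = 6.42e-12, 1.67e-06, 2.87e-05, 8.73e-13 and 1.09e-08 for these 5 results, and adjusted p = 0.109, 0.244, 0.317, 0.1 and 0.161 with an estimated correlation.

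The ecotype comparison, SW against IT over the 4 regimes, had among its named genes CAX3 (AT3G51860), a vacuolar cation exchanger, higher in SW by 2.18 ± 0.36 (adjusted p = 0.000229), AGP15 (AT5G11740), an arabinogalactan protein, by 1.21 ± 0.11, the annexin ANNAT1 (AT1G35720) by 0.98 ± 0.16 and the nitrate transporter NRT1.5 (AT1G32450) by 0.94. SIP2 (AT3G57520), a raffinose-degrading enzyme, was lower at -2.27 ± 0.28 (adjusted p = 2.08e-05), the zinc finger gene OZF1 (AT2G19810) at -1.34 and the chloroplast RNA-binding gene CP29 (AT3G53460) at -0.99 ± 0.09. In all 4286 genes differed, 2157 higher and 2129 lower in SW, and 2402 in the additive model with the library series. CAX3 stood at 132 ± 86.4 CPM in SW_LLC and at 15.1 ± 1.23 CPM in SW_LLW (SD, n = 3). Because each label holds 2 groups of each transcript set, this comparison averages over the sets. FLC, the repressor of flowering that vernalization silences, differed by 0.73 (adjusted p = 0.0831), CBF2 by -0.37 (adjusted p = 0.384), CBF3 by -0.56 (adjusted p = 0.367) and PSBS by 0.11 (adjusted p = 0.52); CBF1 was at the table's lowest value in both LLW groups and its fold is not given. FLC passed the test with DESeq2 at 0.74, without IT_LLW replicate 2 at 0.60 and without IT_HLW replicate 2 at 0.98.

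Ribosome biogenesis genes were lower in SW for 11 of 12, with NAP57, a pseudouridine synthase, at -1.16 ± 0.11 and NUC1, nucleolin, at -0.95 (camera adjusted p = 3.59e-09; adjusted p = 0.242 with an estimated correlation). This direction did not hold for all members in LLW. NAP57 was at 6.18 ± 0.91 CPM in SW_LLW and 2.71 ± 0.409 CPM in IT_LLW (SD, n = 3). Group means of NOP56, FIB1, RH7, BRX1-2 and REIL2 were also higher in SW_LLW, and that of REIL1 was lower. The call of NAP57 was lost in the additive model with the library series, where it stood at -1.05. That model also leaves out the difference between ecotypes in light by temperature. Dark-induced genes were lower for 7 and higher for 1 of 12, 10 lower adjusted over the list alone, with DIN10 and SEN1 both at -1.46. Cold-regulated genes were lower for 10 and higher for 2 of 29, with COR15A at -1.87 ± 0.26 and GOLS2, a galactinol synthase, at 1.74. Against other genes, camera returned adjusted p = 0.00894 and 0.0213 for these lists, and adjusted p = 0.534 for both with an estimated correlation. Genes with a mean under 0.1 CPM over the groups of one label and over 1 CPM over those of the other were few. There were 6 expressed in SW and 4 in IT, and each of those named had a mean over 1 CPM in 1 group. In SW, BGLU28 was at 6.31 ± 8.98 CPM and PAP25 at 5.22 ± 5.56 CPM in SW_HLC, and AT5G07650 at 5.63 ± 3.97 CPM in SW_LLC. In IT, LEA4-5 was at 7.79 ± 13.2 CPM, HSFA6A at 7.20 ± 12.4 CPM and ATMG00285 at 5.13 ± 8.79 CPM in IT_HLC (SD, n = 3). The last 3 rest on 1 library each, with 98.8%, 99.4% and 99.2% of the group's sum in its highest library, and BGLU28 and PAP25 had 87.7% and 71.4% there.

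The sign of the ecotype difference turned between regimes. In LLW, photosystem subunits were lower in SW for 15 of 29, 18 adjusted over the list alone, and antenna genes for 10 of 21, 12 adjusted over the list alone; in HLC photosystem subunits were higher in SW for 17, 22 adjusted over the list alone, antenna genes for 8, 13 adjusted over the list alone, and phloem markers for 8, 9 adjusted over the list alone. Camera gave adjusted p = 1.38e-05 and 0.000612 in LLW, adjusted p = 0.837 for both with an estimated correlation. In HLC it gave adjusted p = 1.3e-07, 5.15e-06 and 2.02e-05, with adjusted p = 0.526, 0.526 and 0.427 with an estimated correlation. Without IT_HLC replicate 2, 6 photosystem subunits, 5 antenna genes and 6 phloem markers were higher in SW in HLC (camera adjusted p = 4.19e-05, 4.47e-05 and 4.19e-05). RPP5 was at 103 ± 5.97 CPM in SW_LLW and 13.9 ± 1.13 CPM in IT_LLW, and at 11.8 ± 1.34 CPM in SW_HLC and 136 ± 29.2 CPM in IT_HLC (SD, n = 3). Between the LLW and HLC differences r was -0.65 across 17709 genes (Spearman -0.53), and 1038 genes were higher in SW in LLW and lower in HLC, where independent lists would share 271. The 2 differences share no library, and genes are not independent replicates. LLW and HLC differences were past the test for 4516 and 4314 genes, the latter 2740 without IT_HLC replicate 2.

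**Figure D5:**
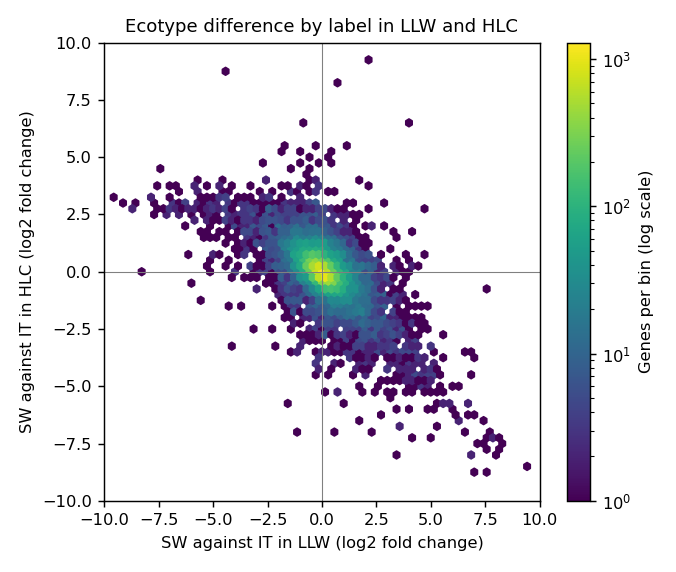
Log2 fold change of SW against IT in LLW (horizontal) and in HLC (vertical) for 17709 genes, binned, with color as genes per bin on a log scale and axes limited to 10 in both directions. The cloud runs from upper left to lower right (r = -0.65).

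In LLC, 7571 genes differed between labels (4021 higher, 3550 lower in SW), and 15 of 16 salicylic acid genes were higher in SW (camera adjusted p = 4.55e-08; adjusted p = 0.41 with an estimated correlation), with PR2 at 898 ± 613 CPM in SW_LLC and PR5 at 791 ± 525 CPM (SD, n = 3). Cold-regulated genes were lower for 14 and higher for 4, and glucosinolate genes lower for 13 and higher for 2, 15 lower adjusted over the list alone (camera adjusted p = 0.0206 for both; adjusted p = 0.806 with an estimated correlation). In HLW, 4317 genes differed (1807 higher, 2510 lower), 9 salicylic acid genes were lower, 10 adjusted over the list alone, and 5 of 6 epidermis markers were higher, with CER1 at 52.5 ± 19.9 CPM in SW_HLW (SD, n = 3). In camera the values were adjusted p = 0.000207 and 0.000672, and adjusted p = 0.537 and 0.417 with an estimated correlation. Ribosome biogenesis genes were lower in SW for 11 of 12 in both LLC and HLW, with 1 higher in HLW adjusted over the list alone (camera adjusted p = 2.29e-07 and 5.85e-07; adjusted p = 0.41 and 0.343 with an estimated correlation).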

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

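The tests that weigh explanations and the other divisions of the libraries were chosen after the results were seen, and the tests of differences were planned.

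The results below were picked out because a test of the difference itself passed, between the ecotype labels or between light levels. The difference between labels in HLC against LLW coincides with the transcript sets. In HLC against LLW 6566 genes differed between labels, with WRR4 at 6.93 on the log2 scale, FH6 at 3.03, ERDL6 at 2.81, P5CR at 2.73 and AAK6 at 2.12 in one direction, and RPP5 at -6.41, SNC1 at -3.91, RPP4 at -3.72, HPA1 at -2.86 and CNGC12 at -2.68 in the other. In light by temperature 6542 genes passed, with PAP12 at 3.84, GATA4 at 3.44, DiT2.2 at 2.81, EBF1 at 2.40 and ERS1 at 2.14, and KCS12 at -5.66, MC3 at -2.09, PRR7 at -2.06, ERDL6 at -2.03 and CRK2 at -1.76. In ecotype by light 6719 genes passed, with BT1 at 4.80, DJ1F at 2.40, P5CR at 1.38, GSNAP at 1.24 and AAK6 at 1.2, and FUT4 at -4.34, RPP5 at -3.50, SNC1 at -2.29, RPP4 at -2.11 and CNGC12 at -1.66. In ecotype by temperature 4440 genes passed, with WRR4 at 4.03, NPR3 at 3.15, FH6 at 1.93, ERDL6 at 1.75 and P5CR at 1.35, and KIN2 at -3.73, RPP5 at -2.91, TET3 at -1.54, HPA1 at -1.48 and TOR1 at -1.36.

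The sign of the SW against IT difference turned between LLW and HLC. A regime that alone switched the set transcripts would leave both labels alike within a regime, yet of 80 transcripts chosen in the LLC and HLW libraries alone, 45 were on in one label and off in the other in both LLW and HLC, 0 were alike and 35 were neither, with IT_HLC replicate 3 set aside (25 opposite with it kept). The 45 are the 28 of the first set and the 17 of the second, whose first choice had used the LLW and HLC values. The choice of the 80 had not used them. An exchange of ecotype labels in LLW or HLC stays open. Of 152 transcripts opposite between labels in LLW, 0 were opposite in both LLC and HLW, so these give no reference for the labels. A different response of each ecotype with all labels right stays open: 0 on and off transcripts followed the labels, but no marker of either ecotype was used here. Which regime, and which set belongs to which ecotype, cannot be read from these data, and an exchange there leaves both LLC groups with the first set and both HLW groups with the second.

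IT_HLC replicate 3 held both transcript sets. Reads passed alike into all libraries of the letter series cannot be the whole cause. The 35 transcripts chosen without SW_LLW and IT_HLC, the 17 of the second set among them, reached 32.7% of their usual level here. In the other 5 libraries of SW_LLW and IT_HLC they reached at most 1.28%. RNA of plants of both kinds in one library stays open. The median place of IT_HLC replicate 3 was taken between the other IT_HLC libraries (0) and the SW_HLC libraries (1). It was 0.284 on 98 genes higher in SW_HLC and 0.626 on 94 genes higher in IT_HLC. All were chosen without this library and outside the sets. A mixture of these groups alone would give equal places. Yet SW_HLC replicate 3, which carries only the second set, had median places of 0.632 and 0.995 when placed the same way. SW_HLC replicates 1 and 2 had 1.107 and 0.995, and 1.061 and 1.0. Unequal places thus arise without both sets, and the difference of 0.342 does not decide. A transfer of reads into this library alone was not tested and stays open, as does the step at which RNA would have been combined. No biological explanation was tested.

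The library group labelled SW_LLC had the highest mean of the defence gene PR1, 1340 ± 828 CPM, and a COR15A mean of 0.95 ± 0.144 CPM, against 61.1 ± 14.6 CPM in IT_LLC (SD, n = 3). A difference between library series cannot be the whole cause, since SW and IT in LLC belong to 1 series and differed in 7571 genes. Exchanged labels of SW_LLC and IT_HLW could place the groups otherwise, but the cold list had a median of 0.03 between them, with 5 members higher and 6 lower, which decides nothing. Exchanged labels of IT_LLC and SW_HLW would make SW_HLW the cool group. The cold list had a median of -1.15 in SW_HLW against IT_LLC (quartiles -2.32 and -0.14). Of 29 members 24 were below 0, with 2 called higher and 11 called lower. These values would count against this exchange only if cool air raises the list in low light. Such a rise was given above only for IT_LLC, whose label is in question here. The values therefore do not decide, and this exchange stays open. An effect of the ecotype in cool low light and an infection of these plants were not tested and stay open.

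For 12 results the real division of the 24 libraries was set among random ones, 100 in all. In each only the real division, 1 of 100, gave as many genes. The random divisions mixed regimes and labels within a group, which widens the spread within it. They show that the 8 groups are not a chance division of the libraries. Light, temperature and the ecotype label were not tested one by one in this way. The real and the highest other counts were 6566 and 1234 for the difference between labels, 8556 and 1443 for light, 9992 and 1533 for temperature, 6542 and 1854 for light by temperature, 4286 and 19 for SW against IT, 6719 and 990 for ecotype by light, and 4440 and 1151 for ecotype by temperature. For results added after the data were seen they were 9881 and 308 for the mean of HLC against LLW, 6002 and 1048 for light in IT, 8995 and 11 in SW, 8696 and 1911 for temperature in IT, and 7113 and 31 in SW.

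Comparisons of 3 libraries with 3 allow 10 divisions, too few for a share under 0.05. The real and the highest other counts were 9678 and 1 for HLC against LLW in IT and 8912 and 1 in SW; for SW against IT they were 4516 and 1 in LLW, 7571 and 5 in LLC, 4317 and 0 in HLW and 4314 and 10 in HLC. From LLW to LLC they were 7146 and 1 in IT and 7117 and 867 in SW, from LLW to HLW 3893 and 2 in IT and 7574 and 0 in SW, from LLC to HLC 7107 and 2 in IT and 9290 and 0 in SW, and from HLW to HLC 7940 and 91 in IT and 7203 and 1 in SW. Added ones were 7313 and 4 for IT_HLC against SW_LLW, 8200 and 1 for SW_HLC against IT_LLW, and 7385 and 2183 for IT_HLW against SW_LLC.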

How the results depend on the processing

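Settings chosen after the data were seen were the offset changes, the mean over both labels, the contrasts within one label, those with the LLW groups exchanged, IT_HLW against SW_LLC, and the list tests of differences between labels and without single IT_HLC libraries. List tests on the single-factor steps and on SW against IT in each regime were not among the planned ones. No named gene reversed, but which direction held more calls turned for several results, among them light by temperature (3051 higher and 3459 lower with DESeq2) and SW against IT in LLW (2024 and 2562). DESeq2, RLE size factors, no filter on low counts, removal of organelle and ribosomal RNA genes, 1 subtracted from every value, and values of 1 set to 0 left every count of changed genes within 1.5 times its value. Fits to 6 libraries, run only for HLC against LLW, gave 7304 genes in IT and 9349 in SW. DESeq2, which changes the test as well as the scaling, moved the share of higher calls by at most 6.8 points, in SW against IT in LLW, where RLE size factors gave 45.6% against 50.9%. Either moved the median of all genes by at most 0.053. The 2 alternatives for normalized values, another pseudocount and a filter on values, were not run because the table holds counts.

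The threshold of an absolute log2 fold change of at least 1 lowered the counts by construction: HLC against LLW 5622 in IT, 4772 in SW and 4069 in the mean; light 2042, temperature 2675, light by temperature 3149; SW against IT 431, in LLW 2384, LLC 3702, HLW 2105 and HLC 2255; ecotype by light 3447 and by temperature 2266. The steps gave 3820 and 3343 for LLW to LLC, 1797 and 3934 for LLW to HLW, 3581 and 5074 for LLC to HLC and 4309 and 3587 for HLW to HLC, in IT and SW; light in IT gave 1889 and temperature in SW 2292. The additive model with the library series, which also drops the difference between ecotypes in light by temperature, gave 2402 for SW against IT. The cause of that lower count was not tested. With the series fitted apart, 1230 genes met the rule for light and 2300 the rule for temperature. A gene had to pass both fits, and light and temperature change together in each. The fit of the number series also coincides with the transcript sets. These counts are therefore not like those of the mean effects. Lists past the camera threshold with an estimated correlation went from 10 to 0 for HLC against LLW in IT, 6 to 0 in SW, 10 to 2 for light, 12 to 1 for temperature and 3 to 0 for SW against IT. Leaving out each library, SW against IT in HLC ranged from 2740 without IT_HLC replicate 2 to 5068 without IT_HLC replicate 3, and no other count moved by over 1.5 times.

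Libraries with the same replicate number did not deviate together (mean r = -0.006 over 84 pairs, -0.36 to 0.31, with 20 over 0.1), so the numbers give no pairing. The replicate block gave 9521 genes for HLC against LLW in IT and changed no count by over 1.5 times. Of 447 results for named genes, 25 lost the call and 17 gained one without some library, 10 lost it with no filter, and 26 of 329 lost it in the additive model with the library series. Depth limits the genes at the table's lowest value in a group, which allow only a bound.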

Other observations

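FLC and SOC1 were picked out after their values were seen, and no test was run on how they go with the transcript sets. Of the other flowering genes with values per group, MAF1 and MAF3 were higher in every group with the first set (MAF1 20.7 to 27.9 CPM against 9.7 to 11.8 CPM), SVP was so except in SW_HLC, and FRI, VIN3 and FUL overlapped. FLC, which represses flowering, was at 69.4 ± 4.22 CPM in SW_LLW, 45.4 ± 3.32 CPM in SW_LLC, 38.5 ± 13.4 CPM in IT_HLC and 32.8 ± 3.85 CPM in IT_LLC, the 4 groups with the first set. In the other 4 groups it was at 19.9 ± 15.7 CPM in IT_LLW, 16.8 ± 8.06 CPM in SW_HLW, 10.1 ± 3.17 CPM in SW_HLC and 2.68 ± 2.18 CPM in IT_HLW (SD, n = 3). SOC1, which FLC represses, had means of 0.559, 3.55 and 8.58 CPM in SW_LLW, SW_LLC and IT_LLC, against 15.3, 34.4, 18.6 and 31.9 CPM in IT_LLW, IT_HLW, SW_HLW and SW_HLC; its mean in IT_HLC lay between those of IT_LLW and SW_HLW.

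STP1, DIN10 and SEN1 were noticed to be higher in IT_LLW than in SW_LLW. The hexose transporter STP1 was at 709 ± 137 CPM in IT_LLW and 41.8 ± 3.02 CPM in SW_LLW, DIN10 at 1030 ± 302 CPM and 34.4 ± 12.6 CPM, and SEN1 at 230 ± 59.7 CPM and 4.29 ± 0.431 CPM (SD, n = 3). Of 12 dark-induced genes 9 were lower in SW_LLW and none was higher, and adjusted over the list alone 2 were higher (camera adjusted p = 1.77e-05; adjusted p = 0.381 with an estimated correlation). The plastid transcript psbA took 19.03% ± 4.94 of counts in IT_HLC and 22.77% ± 1.8 in SW_HLC, against 30.15% ± 2.1 in IT_LLW and 30.77% ± 2.46 in SW_LLW (SD, n = 3).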
